A study of Mus musculus with 6 samples.

How the data were processed

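Gene expression was measured in 6 samples of total RNA from mouse embryonic stem (ES) cells of the E14Tg2a line, 3 labelled control and 3 labelled REST KO, each hybridised to 1 array of an Illumina MouseRef-8 v2 bead chip. On these arrays each transcript is read by a 1-colour probe carried on many beads, with a mean of 40 to 40.2 beads per probe and array. The mean intensity per probe was made by the authors in BeadStudio 3.3.7 with no normalization, per the file headers. A detection score per probe and array was deposited beside it. Its column is headed as a p-value, but the score rises with the signal, so 1 minus the score was used as the detection p. The authors also deposited log2 values, and these differed from quantile normalized log2 intensities without background correction by at most 5e-09. Their own comparison, a deposited table of log2 fold changes with p-values made with limma, per the labels, was used only for the counts credited to it. The name of that table calls the comparison group Rest flox, where the sample labels say only control. The labels' design text names beadarray and limma. The model options behind that table are not given in the sources used here, nor is the genome build of its gene positions, so chromosomes are the only positions printed.

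From the intensities, background was corrected with a normal-exponential model that uses the detection p in place of negative control probes, an offset of 16 was added, and the arrays were quantile normalized on the log2 scale (neqc in limma 3.58.1, R 4.3.3). The offset pulls fold changes of dim probes toward 0. Probes with a detection p under 0.05 on at least 3 of the 6 arrays were tested, which kept 11388 of 25697 probes for 8636 genes. The test was limma's lmFit and eBayes on genotype alone, two-sided, with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Adjusted p values for probes and genes come from that fit unless another fit is named. A probe not detected on any array of a genotype has only a bound there. For these the fold is given as "at least", against the higher of the lowest detected level and the probe's own value on each array. Where only some arrays of a genotype detect a probe, its fold change averages in background values. Errors of fold changes are standard errors of that fit, and errors of levels are standard deviations over 3 arrays.

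Genes were named by the symbols in the authors' deposited table, updated through the RefSeq gene table of assembly GRCm38.p6, and otherwise by the array's target names. This gave a current symbol to 22049 probes from the authors' symbols and to 3118 from target names, and left 202 and 328 probes with the older name. For 84 probes the symbol and the target name pointed to different genes, and the authors' symbol was kept. Where a gene has several probes, its brightest tested probe stands for it.

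A set of 20 gene lists was written from general knowledge before the data were examined. Each was tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the 20 lists. The same lists were also tested with a correlation estimated per list, and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The genes named in the text were taken from a set fixed by rule at the same time. The set holds Rest, the 12 largest rises and 12 largest falls among called genes whose arrays do not overlap between genotypes, up to 4 called members per list by smallest adjusted p, and Pou5f1, Nanog and Sox2. Predicted and unnamed transcripts were skipped among the largest changes. Any other gene named was chosen after its values were seen, as an example from a list or because its control arrays disagree.

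The script was tested on simulated data with the probe means and spreads of the REST KO against control comparison (11388 probes). It recovered 15.2% of probes changed by 0.5 on the log2 scale, 91% of those changed by 1 and 100% of those changed by 2, with 15 false calls. Probes were drawn independently, so these rates do not cover shifts of many probes on 1 array. In the data the brightest probe of Mest differed by 3.94 on the log2 scale and was not called. On 11188 simulated genes, those left unchanged in that simulation, the list test called the 1 shifted list and 0 of 19 others. These genes were drawn independently, so this does not show how the list test behaves where genes of a list move together. In the data the estimated correlation was 0.579 on the REST target list and 0.679 on the primed epiblast list. The number of arrays, 3 per genotype, limits the precision of every value.

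The labels do not say whether the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicate arrays differed by more than the bead error, with a lowest mean squared difference of 2.28 times that error, so no pair was merged. The 3 control arrays lay on the first 3 positions of 1 chip and the REST KO arrays on the last 3, so chip position and genotype cannot be told apart. The alternatives tried were quantile normalization without background correction, cyclic loess, an offset of 50, the authors' log2 values, no filter and a stricter filter on dim probes (detection p under 0.01 on all 6 arrays), eBayes with trend and robust options, array weights, the replicate number as a block, leaving out each array in turn, the mean of a gene's probes, and the estimated correlation and fry for lists. Bead numbers served only to describe depth and bead error. Gene positions other than the chromosome were not used.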

Results

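REST (RE1-silencing transcription factor, encoded by Rest) is a zinc-finger repressor that binds RE1 elements and keeps many neuronal genes silent outside neurons. Expression in Rest-null mouse ES cells was compared with control cells of the same line, E14Tg2a, an Hprt-deficient line that grows without feeder cells, to ask how the loss of REST alters the ES cell transcriptome. Each genotype had 3 arrays. Between 42.5% and 44.9% of probes were detected per array, and the median raw signal lay between 120.5 and 132.8.

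Rest itself could not be used to check the labels. Its single probe, on chromosome 5, was detected on none of the 6 arrays, with a level of 5.01 ± 0.09 (log2, SD, n = 3) in control and 4.96 ± 0.11 in REST KO cells. The log2 difference was -0.05 ± 0.09 (SE). Both levels are background, so no fold is given, and the labels do not say which exons were deleted.

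In REST KO cells 120 probes rose and 25 fell, so 82.8% of the 145 called probes were higher, and of the 83 that also changed at least 2-fold 77 rose. This majority depends on the fit: 49.5% of the called probes were higher without control replicate 2 (815 higher and 832 lower), 52.7% with array weights (730 and 656) and 68.8% with the stricter filter (86 and 39). By the brightest probe of each gene, 96 genes rose and 22 fell. Gdap1, which encodes a mitochondrial outer membrane protein of neurons, rose by 2.66 ± 0.41 on the log2 scale (SE, n = 3 per genotype, adjusted p = 0.0384), but only 1 of 3 control arrays detected it, so that difference is in part against background. The growth factor gene Bdnf, a known REST target, rose by 1.79 ± 0.20 (adjusted p = 0.0239).

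Other large rises were of several kinds. Signalling and developmental regulators included Wnt8a (log2 2.36 ± 0.33), Fgfbp1, which releases fibroblast growth factors from the matrix (2.28 ± 0.27), the helix-loop-helix inhibitor Id1 (2.00 ± 0.21) and the hindbrain gene Hoxb1 (1.91 ± 0.27). The orphan receptor gene Gpr158 rose by 1.98 ± 0.26, and the myelin protein gene Pmp22 by 1.86 ± 0.17. Genes of cytoskeleton, matrix and junctions were Acta2, smooth muscle actin (2.03 ± 0.31), Tnc, tenascin C (1.94 ± 0.22), and the tight junction gene Cldn5 (1.75 ± 0.23). Car3, a carbonic anhydrase, rose by 2.43 ± 0.38. Adjusted p values of these 12 genes ran from 0.0239 to 0.0384. Of the 3 control arrays 1 detected Car3, Gpr158 and Tnc and 2 detected Bdnf, Wnt8a, Fgfbp1, Hoxb1 and Cldn5, so background values enter their differences.

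Falls were smaller. Tet2, which oxidises 5-methylcytosine, was at least 1.69-fold lower in REST KO cells, where no array detected it (adjusted p = 0.0427). The ketone body enzyme gene Bdh2 fell by 1.25 on the log2 scale (SE 0.20), Gfod1 by 1.23, Enpp4 by 1.16 and the salt-inducible kinase gene Sik1 by 1.09. Stag3, a meiotic cohesin subunit, fell by 0.96, and the signal transducers Stat6 and Stat4 fell by 0.90 and 0.85. Lin7b fell by 0.88. Some REST KO arrays did not detect Gfod1, Enpp4, Stat6 (2 of 3 detected each) and Sik1 (1 of 3). Megf11, the non-coding transcript Platr26 and the endoderm regulator Sox7 were detected on no REST KO array, and were at least 1.58-fold, 1.53-fold and 1.43-fold lower. Zeb1, a zinc-finger repressor, fell by 0.63 (adjusted p = 0.0468).

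**Figure D1:**
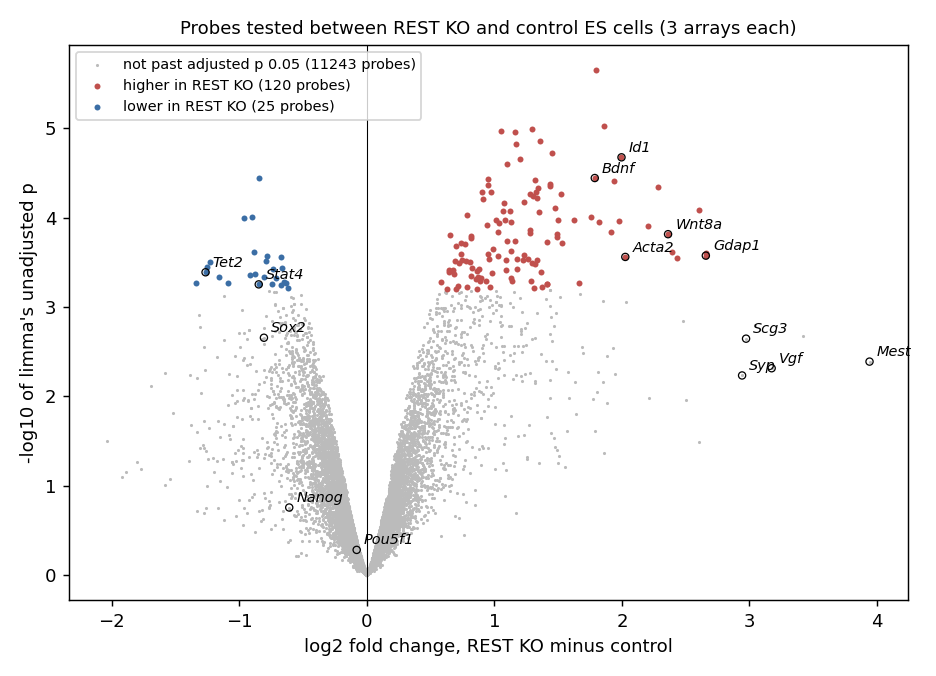
Each point is 1 of the 11388 tested probes, with the log2 fold change of REST KO minus control on the x axis and -log10 of limma's unadjusted p on the y axis. The 120 probes that rose (red) and the 25 that fell (blue) are coloured, and Mest, Vgf, Scg3 and Syp lie by their brightest probes farther to the right than any called probe without passing the threshold.

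The call count depends on single arrays. Without control replicate 1, or without any 1 of the REST KO arrays, limma called 0 probes (1449 to 2086 had an unadjusted p under 0.05), whereas it called 1647 without control replicate 2 and 250 without control replicate 3. Control and REST KO arrays did not overlap in 2859 tested probes (25.1%, where chance gives 10%), the 145 called ones among them.

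The REST target list holds neuronal genes taken from general knowledge as REST targets, and their RE1 elements were not mapped here. Of its 24 tested genes 4 rose and none fell, 23 had a log2 fold change above 0, and the median was 1.20. Adjusted over the list alone, 19 rose. Counts over the list alone, for this and every other list, were not adjusted over the 20 lists. Among all 11388 tested probes 2262 had an unadjusted p under 0.05 in the same limma fit. Such a count therefore does not by itself set a list apart from other genes. The camera test placed the list above other genes (adjusted p = 1.46e-12), but not with an estimated correlation, where the adjusted p = 0.345. The number that rose ran from 1 (of 48 with no filter) to 11 under other normalizations, filters and eBayes options. With no filter 35 of the 48 were above 0, with a median of 0.11. The filter admits genes detected only on the REST KO arrays, and 14 of the 24 tested genes were detected on all control arrays. The called members were Bdnf, Gdap1 and the scaffold protein genes Mapk8ip2 (log2 1.18 ± 0.19, adjusted p = 0.0416) and Mapk8ip1 (0.83 ± 0.13). Larger differences that did not pass were those of the neuropeptide precursor gene Vgf (3.17 ± 0.80, adjusted p = 0.0953), the granin gene Scg3 (2.97 ± 0.65, adjusted p = 0.0721) and the synaptic vesicle gene Syp, synaptophysin (2.94 ± 0.77, adjusted p = 0.102). In these 3 genes control replicate 3 lay between the other controls and the REST KO arrays. Scg3, for example, was at 5.00 and 4.98 in control replicates 1 and 2, 7.59 in control replicate 3, the only control array that detected it, and 8.83 ± 0.04 in REST KO cells. Not all members were higher: Stmn2 (0.02 ± 0.24) and Celf4 (0.05 ± 0.16) had log2 fold changes near 0, and Scn3b had -0.21 ± 0.17.

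Averaged over the REST target list, control replicate 3 stood at 7.96, against 6.78 and 6.76 in the other controls and 8.55 to 8.59 in the REST KO arrays, and the number of members that rose was 17 without control replicate 3, 10 without control replicate 2 and 0 without control replicate 1 or any 1 of the REST KO arrays.

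**Figure D2:**
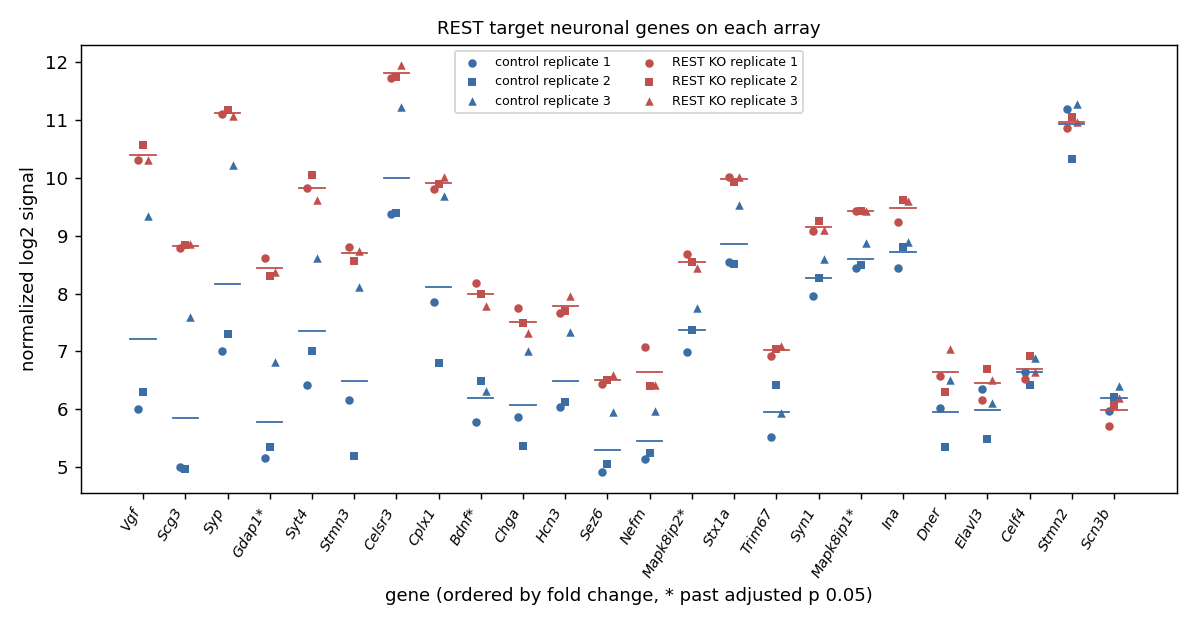
Normalized log2 signal (y axis) of the 24 tested REST target genes (x axis, ordered by fold change) on each of 3 control (blue) and 3 REST KO (red) arrays, with lines at the group means and asterisks on genes past an adjusted p of 0.05. In 19 genes all REST KO arrays lie above all controls, and control replicate 3 (blue triangles) is the highest control in Vgf, Scg3, Syp and Celsr3.

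Other neuronal groups overlapped with this list in part. Among 15 synaptic vesicle and exocytosis genes 1 rose and none fell, and 6 rose adjusted over the list alone. The called gene was Slc17a6, the vesicular glutamate transporter VGLUT2, which no control array detected and which was at least 2.04-fold higher in REST KO cells (adjusted p = 0.0274). Without control replicate 3, 7 synaptic genes rose, and without control replicate 2, 4 rose and 1 fell. Without control replicate 1 or any 1 of the REST KO arrays none passed. Of 19 genes of the neuronal cytoskeleton and differentiation none passed (6 rose adjusted over the list alone), with Gap43 at 1.37 ± 0.32 (adjusted p = 0.0844) and the tau gene Mapt at -0.97 ± 0.47 (adjusted p = 0.305). Without control replicate 2, 5 of the 19 rose and 1 fell, and without control replicate 3, 3 rose. Among 10 ion channel and receptor genes 1 rose and none fell, 4 rose adjusted over the list alone, and the list was not called (adjusted p = 0.0991). Of 9 neural progenitor genes none passed and 4 rose adjusted over the list alone, among them Nes, nestin, at least 1.49-fold higher (adjusted p = 0.0504), and Insm1 (1.93 ± 0.44, adjusted p = 0.0798). Without control replicate 2, and also with array weights, 5 of the 9 rose. With no filter 17 of 34 neural progenitor genes were above 0, with a median of 0.0045. The camera test called the synaptic (adjusted p = 0.000672), cytoskeleton (0.000252) and neural progenitor (0.00408) lists upward, each with an adjusted p = 0.345 with an estimated correlation. Single controls lay toward the REST KO arrays: control replicate 3 on the synaptic list (mean 7.91, against 7.25 and 7.26 in the other controls and 8.24 to 8.31 in REST KO arrays) and the cytoskeleton list (7.76, against 7.41 and 7.12, and 7.91 to 7.97), and control replicate 2 on the neural progenitor list (8.14, against 7.23 and 7.48, and 8.20 to 8.51). Of 5 astrocyte and oligodendrocyte genes none passed (median 0.14, adjusted p = 0.36).

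Core pluripotency factors were not called. Pou5f1 stood at 12.86 ± 0.12 (log2, SD, n = 3) in control and 12.78 ± 0.13 in REST KO cells (log2 fold change -0.08 ± 0.12, adjusted p = 0.75), and its dimmer probe at -0.42 ± 0.11 (adjusted p = 0.104). Nanog had -0.61 ± 0.40 (adjusted p = 0.442) and Sox2 had -0.81 ± 0.17 (adjusted p = 0.0714) by its brighter probe and 0.07 ± 0.17 by the other. Of 31 pluripotency genes none passed, 3 fell adjusted over the list alone (Pecam1, Sox2 and Nr5a2), 8 had a fold change above 0, and the median was -0.36. Members ran from Klf4 (-1.54 ± 0.77, adjusted p = 0.313) to the Nodal target Lefty2 (0.89 ± 0.25, adjusted p = 0.122).

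Of 14 tested genes of the primed, epiblast-like state 2 rose and none fell, and 5 rose adjusted over the list alone, with 13 above 0 and a median of 1.03. With no filter 15 of 21 were above 0, with a median of 0.68. The list was called upward (adjusted p = 5.54e-06), but neither with an estimated correlation (adjusted p = 0.365) nor with fry (adjusted p = 0.0914). The called genes were Wnt8a and the keratin gene Krt18 (1.53 ± 0.22, adjusted p = 0.0337). Pou3f1 had 1.80 ± 0.51 (adjusted p = 0.122) and Otx2 1.17 ± 0.84 (adjusted p = 0.477). The pluripotency list was called downward (adjusted p = 0.0421), but neither with an estimated correlation (adjusted p = 0.506) nor with fry (adjusted p = 0.225).

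Control replicate 2 lay near the REST KO arrays on both lists. Its primed list mean was 8.91, against 7.36 and 7.63 in the other controls and 8.82 to 9.27 in REST KO arrays, and its pluripotency mean was 10.69, against 11.22 and 11.27 in the other controls and 10.59 to 11.01. Without it 13 primed genes rose, and 13 pluripotency genes fell and 3 rose, Nanog among those that fell (log2 -1.06, adjusted p = 0.0386). The call of the pluripotency list was lost without control replicate 1 (adjusted p = 0.115), control replicate 3 (0.21) and REST KO replicate 1 (0.131) or 2 (0.0951).

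**Figure D3:**
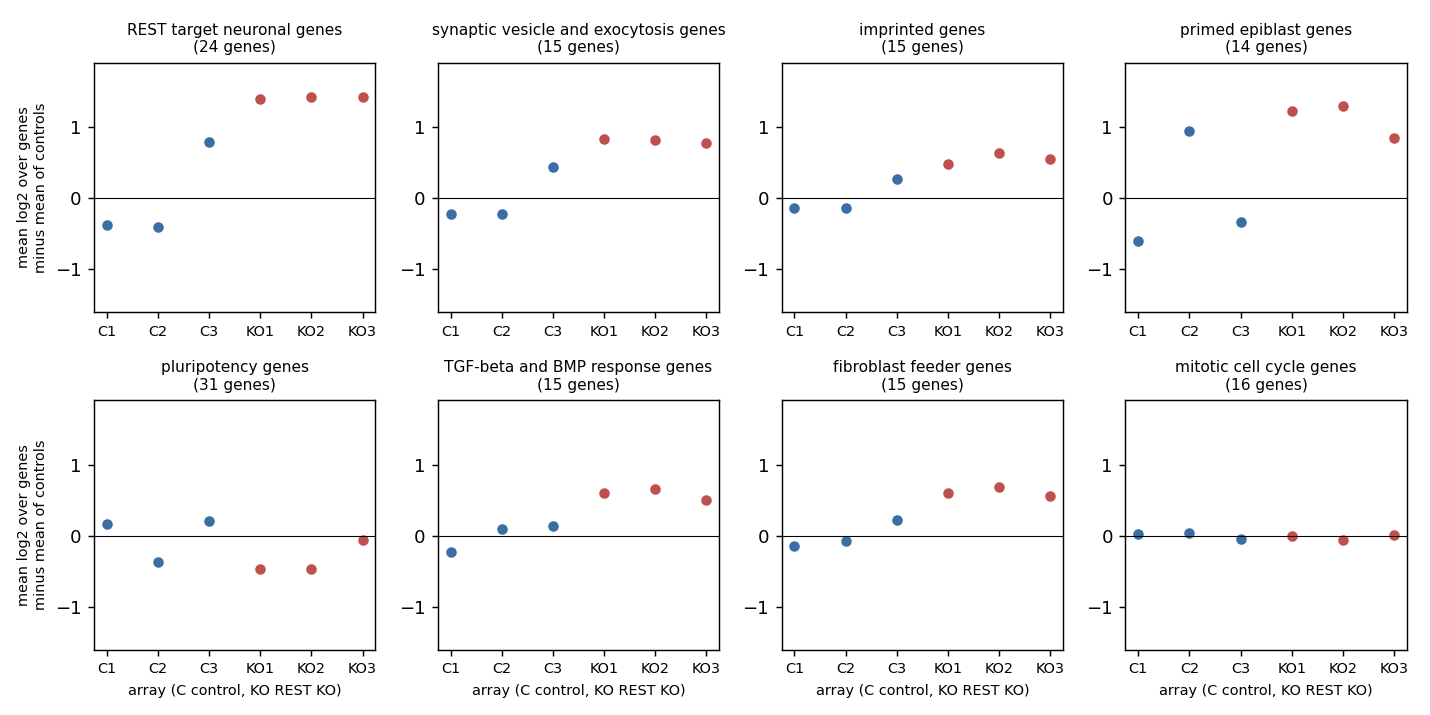
Mean log2 signal over the tested genes of 8 lists on each array, minus the mean of the 3 control arrays (y axis), for control (C, blue) and REST KO (KO, red) arrays (x axis). Control replicate 3 stands above the other controls on the REST target list, and control replicate 2 lies near the REST KO arrays on the primed epiblast and pluripotency lists.

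Markers of early lineages were mixed. Of 15 trophectoderm genes 4 rose: the transcription factor genes Gata3 (0.91 ± 0.11), Id2 (1.49 ± 0.21) and Tfap2a (1.31 ± 0.23), and Krt18. Adjusted over the list alone 7 rose and 1 fell. Cdx2, which specifies trophectoderm, had 0.69 ± 0.17 (adjusted p = 0.0977). The list was called upward (adjusted p = 0.00859, and adjusted p = 0.349 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.523). Its mean was 7.63 in control replicate 2, while control replicates 1 and 3 (8.21 and 8.36) lay near or among the REST KO arrays (8.27 to 8.46). Of 6 primitive streak and mesoderm genes Hoxb1 and Fgf8 (1.32 ± 0.21, adjusted p = 0.0391) rose, 2 rose and 1 fell adjusted over the list alone, and the list was not called (adjusted p = 0.199). Of 12 endoderm genes only Sox7 passed, here and over the list alone, and Gata6 had -0.24 ± 0.18. The endoderm list was not called (adjusted p = 0.371), nor were the 17 basement membrane genes (none passed, 2 rose and 1 fell adjusted over the list alone, adjusted p = 0.899), whose median of 0.07 and mean of -0.07 differed in sign.

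Of 15 genes in the fibroblast feeder list Acta2 and Tagln (1.45 ± 0.15, adjusted p = 0.0239, detected on 1 control array), both smooth muscle and actin cytoskeleton genes, rose, and 8 rose adjusted over the list alone, among them the matricellular genes Ccn1 (1.41 ± 0.26, adjusted p = 0.0528) and Ccn2 (1.24 ± 0.26, adjusted p = 0.0658). The surface marker gene Thy1 had -0.06 ± 0.15, and the fibrillar collagen genes Col1a1, Col1a2 and Col3a1 were detected on no array. Of these 15 genes 12 were detected on all control arrays. Of 15 genes responding to TGF-beta or BMP Id1 and Id2 rose, 9 rose adjusted over the list alone, and Id3 had 0.82 ± 0.24 (adjusted p = 0.127). Without control replicate 2, 7 of these 15 rose and 1 fell, and without control replicate 1 none passed. Camera called the fibroblast list (adjusted p = 6.73e-05) and the TGF-beta and BMP list (0.000163) upward, both at adjusted p = 0.345 with an estimated correlation.

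Of 15 imprinted genes none passed by the brightest probe, 7 rose adjusted over the list alone, and 12 were above 0, with a median of 0.34 (camera adjusted p = 0.00219, and adjusted p = 0.345 with an estimated correlation). With no filter 18 of 24 were above 0, with a median of 0.053. Without control replicate 2, 6 of the 15 rose and 1 fell, and with an offset of 50, 3 rose. Mest had the largest difference in the set, 3.94 ± 0.96 (adjusted p = 0.0896), with control replicates at 5.40, 4.96 and 9.02 and REST KO cells at 10.40 ± 0.04, and a dimmer Mest probe rose by 2.66 ± 0.40 (adjusted p = 0.0384). Of the control arrays only control replicate 3 detected Mest. Igf2 had 1.21 ± 0.25 and the cell cycle inhibitor gene Cdkn1c 1.03 ± 0.25 (adjusted p = 0.0668 and 0.0904). Averaged over the imprinted list, control replicate 3 was at 9.65, against 9.23 and 9.24 in the other controls and 9.86 to 10.01 in REST KO arrays.

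Genes encoding the REST corepressor machinery were not called as a group. Of 20, Zeb1 fell (but not with cyclic loess, with no filter, with the replicate block, or without control replicate 1 or 3 or any 1 of the REST KO arrays) and none rose, also over the list alone, with Rcor1 at -0.16 ± 0.16, Kdm1a at 0.02 ± 0.11 and Hdac2 at -0.10 ± 0.11 (list adjusted p = 0.57). None of the 16 mitotic genes passed, also over the list alone (median -0.06, adjusted p = 0.809), nor did any of 20 p53 response genes (2 fell over the list alone, adjusted p = 0.272), 13 germline genes (4 fell over the list alone, Tex11, Smc1b, Stra8 and Piwil2, adjusted p = 0.443) or 20 glycolysis and hypoxia genes (2 fell over the list alone, adjusted p = 0.272). Without control replicate 2, 6 glycolysis and hypoxia genes rose and 4 fell. In that fit 1 rose and 1 fell in each of the p53 and germline groups, and no mitotic gene passed. A p that misses the threshold does not show that these groups were equal in both genotypes.

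Of 25695 probes in the authors' deposited table, 448 passed an adjusted p of 0.05, 331 higher and 117 lower in REST KO cells, and 55 changed at least 2-fold. Of the 145 probes called here 143 were also past the threshold in the authors' deposited table, with the same sign.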

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

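All alternatives reported here were chosen before the data were examined. All 145 called probes kept their direction under each other normalization, and among 896 values of 62 genes followed under these settings 2 reversed, both of Tfap2c, which was not called (log2 -0.56, from -1.83 to 0.10 with 1 array left out, at 0.10 and 0.06 without control replicates 1 and 3). Of the 62 genes 35 were called. Arrays of called probes do not overlap between genotypes, so leaving out 1 array could hardly reverse them. The count of 145 probes became 332 with quantile normalization alone and with the authors' values (50 at least 2-fold in both, against 83), 274 with an offset of 50, 138 with cyclic loess (123 higher and 15 lower), 50 of 25697 probes with no filter (33 at least 2-fold, where 11388 probes passed the filter), 364 with trend and robust options (129 at least 2-fold), 1386 with array weights (312 at least 2-fold, 730 of the 1386 higher), which gave control replicate 2 a weight of 0.31, and 448 in the authors' deposited table. The stricter filter left 30 calls of at least 2-fold, and tested 53 of the 145 probes. With 1 array left out the counts ran from 0 to 1647, and from 0 to 397 for at least 2-fold: 0 without control replicate 1 or any REST KO array, 1647 without control replicate 2 (815 higher and 832 lower, with all 145 probes called) and 250 without control replicate 3 (106 of the 145 called). With the replicate number as a block limma called 0 probes, also at 2-fold, with a smallest adjusted p of 0.0681 and 2376 probes at an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at -0.27, 0.34 and 0.36. Control replicates 2 and 3 correlated best with the REST KO array of their own number, and control replicate 1 with REST KO replicate 3 (0.45). Deviations from means of 3 arrays cannot settle whether the number marks a pair or a batch, so the loss of all calls with the block remains a limit. REST target genes that rose, 4 of 24, numbered 11 with quantile normalization alone, with the authors' values and with array weights, 10 with an offset of 50, 9 with trend and robust options, 4 with cyclic loess, 3 of 8 with the stricter filter, 1 of 48 with no filter and 0 with the block. With an estimated correlation no list was called: the adjusted p was 0.345 for the REST target, synaptic, cytoskeleton, neural progenitor, fibroblast, TGF-beta and BMP, and imprinted lists, 0.349 for trophectoderm, 0.365 for primed epiblast and 0.506 for pluripotency. With fry the cytoskeleton (0.0721), pluripotency (0.225) and primed epiblast (0.0914) calls were lost, and the primitive streak (0.0389) and endoderm (0.00899) lists passed. The ion channel list passed with the mean of a gene's probes (0.0177) and ran from 0.00429 (without control replicate 3) to 0.242 with 1 array left out. The pluripotency list ran from 0.00538 (without control replicate 2) to 0.21 (without control replicate 3). The trophectoderm list ran from 0.000636 to 0.523 (without control replicate 2), was at 0.18 with array weights, and turned downward under the stricter filter (0.828). The neural progenitor list was at 0.107 with no filter. Lists never called that changed direction were basement membrane (0.933 with array weights, 0.952 with the mean of probes, and 0.525 to 0.996 with 1 array left out), astrocyte and oligodendrocyte (0.803 with no filter) and REST corepressor genes (0.377 to 0.996 with 1 array left out, upward at 0.996 without control replicate 2). For each result that did not keep its side, the cause was not tested. Signal over background limits the fold of 22 called probes, 18 detected on no control array and 4 on no REST KO array, and background enters the difference of others, 26 detected on only some control arrays and 5 on only some REST KO arrays.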

Other observations

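All tests in this part were chosen after the values they concern had been seen. The groups of genes in the next paragraph were likewise put together after the fold changes were known, so their tests describe these arrays and are not independent evidence.

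Hox genes had fold changes above 0 without exception: of 9 tested, Hoxb1 and Hoxb2 rose (log2 1.91 ± 0.27 and 1.47 ± 0.19 SE, n = 3 per genotype), with Hoxb5 at 1.12 ± 0.21 (adjusted p = 0.0548), and the camera adjusted p over 6 such groups was 2.91e-06 (0.0897 with an estimated correlation). Of 8 genes of the X-linked Bex and Tceal families, 1 (Tceal5, 1.35 ± 0.17, adjusted p = 0.0274) rose and all 8 were above 0 (adjusted p = 1.46e-06, and 0.117 with an estimated correlation). Of 17 serum response factor and actin cytoskeleton genes, Acta2, Tagln, Tpm1 (1.09 ± 0.17) and Actc1 (0.68 ± 0.11) rose and all 17 were above 0 (adjusted p = 1.05e-11, and 0.117 with an estimated correlation). Among 17 interferon-induced genes Irf1 (0.98 ± 0.16), Oasl2 (1.12 ± 0.14) and Gbp3 (0.81 ± 0.12) rose and 10 were above 0 (adjusted p = 0.0288, and 0.415 with an estimated correlation), with a mean of 7.74 in control replicate 2, while the other controls (8.25 and 8.46) lay within or near the REST KO arrays (8.30 to 8.48). None of 8 granule and neuropeptide genes passed (median 1.44, adjusted p = 0.00019, and 0.169 with an estimated correlation), and control replicate 3 had a mean of 7.24, against 5.85 and 5.77 in the other controls and 7.72 to 7.84 in REST KO arrays. None of 15 LIF and STAT3 response genes passed either (2 above 0, adjusted p = 0.00198, and 0.389 with an estimated correlation). The mean of the LIF and STAT3 group was 8.41 in control replicate 2, against 10.1 and 10.0 in the other controls and 8.28, 8.27 and 9.30 in the REST KO arrays. The sign of each group's median was the same under all 5 scalings, of which quantile normalization alone and the authors' values are nearly identical.

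Outside these groups the proneural regulator Hes6 rose on each of 3 probes (1.79, 1.28 and 1.28), as did the neuronal genes Glra2 (1.49 ± 0.21), Cdk5r1 (1.42 ± 0.20) and Ncan (1.18 ± 0.18). The germ cell genes Sohlh1 and Tex14 fell by 0.71 and 0.67, the former on 1 of 2 probes, and Fmr1nb fell by 0.78. Chromosome medians of the log2 fold change ran only from -0.07 to 0.05 over 20 chromosomes.

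The 6 arrays can be divided into 3 and 3 in 10 ways. Of these, 1 (the real one) gave as many as 145 called probes and 1 as many as 83 at least 2-fold, with 50 and 38 the highest of the others, both in the division that puts control replicate 2 with REST KO replicates 1 and 2. As many as 10 called lists came from 2 of the 10 divisions, the highest other also at 10, in the division that puts control replicate 3 with REST KO replicates 1 and 2. With 10 divisions no share can be under 0.05.

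Control replicate 3 stood between the other controls and the REST KO arrays for many REST targets. In 16 genes chosen without it, whose REST KO arrays all exceeded control replicates 1 and 2 by at least 2 on the log2 scale, its linear signal lay 24.3% to 66.2% of the way to the REST KO mean (median 47.9%). A single share of REST KO cells or RNA is argued against by the spread of these values (chi-square over degrees of freedom 5.55). Among 87 genes with a gap of at least 1, shares ran from -9.36% to 100.1%. Of these, Bdnf (3.91% ± 10.7 SE), Acta2 (8.64% ± 12.2) and Id1 (11.1% ± 6.56) had low shares. They were picked from the 87 genes after their values were seen, so they add no separate test. On the log2 scale Id1 was higher in control replicate 3 (8.38) than in control replicates 1 and 2 (7.66 and 8.12). The errors of the shares take the variation of control replicate 3 from the REST KO arrays (coefficient of variation 8.98%, and 12.4% for the 87 genes). If that control varied more, the errors are too small and the chi-square too large. Exchanged labels would put a REST KO array at the level of the controls and are argued against by the REST target list. Its mean on the lowest REST KO array lay 1.77 above the higher of control replicates 1 and 2 on the log2 scale. The SE of 0.28 is over the genes of the list, which move together, and measures no spread between samples. A lower level of Rest in this sample could not be tested and remains open, because the smallest detection p of the Rest probe on any array was 0.375. The controls may carry a floxed Rest allele, as the name of the authors' table has it. Deletion of that allele in some control cells would itself be a share of REST KO cells. The low share of Bdnf, a known REST target, does not decide on lower Rest, because REST targets need not all respond to the same degree.

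Control replicate 2 stood apart from the other controls, at 3.33 on principal component 1 (57.5% of the variance), against -34.15 and -22.57 in those and 6.42 to 23.49 in the REST KO arrays, and at -29.65 on component 2 (24.5%), away from all other arrays. A mislabelled REST KO array is argued against by its mean over the REST target list, 1.79 below the lowest REST KO array on the log2 scale. The SE of 0.25 is over the genes of the list and measures no spread between samples. In the 2159 brightest genes its differences from the other controls spread 3.03 times as widely as those controls differed from each other (95% bootstrap interval over genes 2.68 to 3.39). So the difference is not confined to dim probes. Weak hybridisation is not decided by this, because its effect on bright probes was assumed and not measured. This array had the lowest median raw signal of the 6 (120.5), while its share of detected probes (42.9%) was above that of REST KO replicates 1 and 2. In this array 12 of 14 primed genes were above both other controls and 22 of 31 pluripotency genes below both. No group of the design bears on culture state, so no biological explanation was tested.

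The higher fibroblast feeder list could come from fibroblasts among the REST KO cells. Of the 3 fibrillar collagen genes Col1a1, Col1a2 and Col3a1, which fibroblasts express abundantly, 0 were detected on any REST KO array (smallest detection p 0.0965), which argues against that source. Thy1 and Fbn1 had log2 fold changes of -0.06 ± 0.15 and 0.04 ± 0.15. They are flat members of a list in which 12 of 15 genes were above 0 and 8 rose adjusted over the list alone, so they decide nothing. The difference between genotypes in actin-associated genes stays open as a biological effect, and chip position, which runs with genotype, cannot be told apart from it.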
